A study of Mus musculus with 12 samples.

How the data were processed

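Values are TPM, a share of transcripts corrected for their length, as deposited by the authors, read from the deposited table that lists 49585 genes in 12 libraries. Per the labels, the cells were RAW264.7, grown in DMEM with 10% FBS. Per the labels, RNA was taken in TRIZOL, and libraries were made from 100 ng of total RNA with NEBNext rRNA depletion and the NEBNext Ultra II Directional kit. The aligner, the counting program and the annotation are not given in the sources used here. The labels name the human build hg19, but the identifiers are mouse Ensembl identifiers, and 49326 of them (99.5%) are in GENCODE M21. No coordinates are given for that reason. Each column sums to 1000000, so sequencing depth cannot be recovered from TPM. Columns were matched to samples by their names, with 0 unmapped. The Mean columns of the table equal arithmetic means (largest gap 5.82e-11). Among genes above 0 in at least 1 library of a pair, no pair of libraries shared an identical value (0%).

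The samples, groups, comparisons, filter, model, gene lists and alternatives were chosen before the data were examined. They were made from the labels alone. Genes with a mean TPM of at least 1 were kept. Values were log2(TPM + 1), fitted with limma-trend (limma 3.58.1, R 4.3.3) in 1 model of 4 groups. Contrasts were Mdivi-1 against no Mdivi-1 at 24 h and at 96 h, the difference of those effects, and 96 h against 24 h without and with Mdivi-1. Every p-value of a gene is from limma, adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The residual degrees of freedom were 8 with 12 libraries. Log2 fold changes on this scale understate changes of genes near or under 1 TPM. They are given with the standard error. TPM values are given as mean with SD.

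Of 50 gene lists written from general knowledge, 47 held at least 5 tested genes. They were tested with camera at a correlation of 0.01. The same test with a correlation estimated from the data and the rotation test fry were run beside it. With few libraries, genes of 1 list share much of their noise, and the estimated correlation allows for it. Plots and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

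The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples. The replicate numbers were checked for pairing by correlating each library's departure from its group mean over genes. At 24 h the libraries with the same number in both groups correlated at 0.968, 0.960 and 0.980, which passes the rule for pairing of a correlation over 0.1 in every pair. Only number 3 is told apart by it, since number 1 reached 0.961 and number 2 reached 0.969 with the other of these numbers, against -0.968 for number 3. The correlations thus follow the departure of both number 3 libraries. Genes are not independent replicates in these correlations.

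Both 24 h libraries with number 3 hold almost no messenger RNA. A fit without them (10 libraries, 19631 genes, 6 residual degrees of freedom) was added after seeing the data, and the results are given first from it, with the planned fit of all 12 libraries beside them. Also added after seeing the data were 24 h libraries 1 and 2 alone with 2 residual degrees of freedom, the same with median-of-ratios scaling, and 96 h libraries alone with 4. The last addition was a background-subtracted table. For that table the median TPM of 1430 olfactory, vomeronasal and trace amine receptor genes was subtracted in each library. Structured RNA, mitochondrial and 13 satellite-like genes were then removed, the rest was rescaled to a sum of 1000000, and 10 was used as pseudocount and filter. Satellite-like genes were those with at least 10% of the 12-base words of their sequence in the major satellite repeat.

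Named genes followed rules. 12 genes fixed beforehand appear in every comparison whose fit tests them, which leaves out Il10. The genes of largest change among those called with a mean of at least 5 TPM and non-overlapping groups were added, as were the leading members of called lists. A test with 100 genes changed by a known factor showed how much each fit can find. With all 12 libraries, the fit found 0 of 100 genes changed 2-fold and at most 1 changed 4-fold in any contrast. Without both 24 h number 3 libraries it found 28 and 96 at 24 h, 66 and 92 at 96 h, 25 and 72 for the difference, and at least 53 and 96 for time. Only genes above 5 TPM were changed, and noise was drawn independently with the same spread in every group. In the data, 24 h libraries 1 and 2 without Mdivi-1 correlated at 0.996, and the 96 h libraries without it at 0.670 to 0.793. The shares found may therefore not hold in these data, above all at 96 h. At 96 h, 12.7% of the calls in that test were false, which was 23 genes. The false share among the 28 genes called in the data at 96 h cannot be read from it. Sample weights did not converge (weights from 0.0195 to 104), so their counts are printed only for completeness.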

Results

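The samples were 12 libraries labelled as RAW264.7, a mouse macrophage-like line from a male BALB/c tumour. All cells received 10 ng/mL LPS, a bacterial signal for Toll-like receptors, and 10 ng/mL mouse IFN-γ. Mdivi-1, an inhibitor of the mitochondrial fission GTPase Drp1, was given at 50 µM in 6 of the libraries from the same time on. Cells were taken at 24 h or 96 h, with 3 libraries in each of 4 groups. Unstimulated cells were not analysed here, so each value describes cells given both stimuli, and how far they were activated could not be measured.

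The libraries differed first in what kind of RNA they held. In 24 h libraries 1 and 2, small structured RNAs such as 7SL made up 47.0% and 46.7% of the TPM total without Mdivi-1 and 49.6% and 52.9% with it. All other genes, which include nearly all messenger RNA, made up 47.5%, 48.1%, 44.1% and 40.4% in the same libraries. Mitochondrial ribosomal RNA took 3.37% to 4.56% there, but 53.1% to 74.2% in the 6 libraries of 96 h. All other genes were left with 7.34% to 12.8% at 96 h. In both 24 h libraries with number 3, mitochondrial ribosomal RNA took 91.6% and 90.8%, and all other genes 1.66% and 0.829%. Olfactory, vomeronasal and trace amine receptor genes, silent in macrophages, had a median of 0 in 24 h libraries 1 and 2 and of 0.498 to 2.7 TPM at 96 h. They had 0.364 and 0.114 TPM in the number 3 libraries. Satellite-like genes took 7.35% to 24.0% at 96 h.

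**Figure D1:**
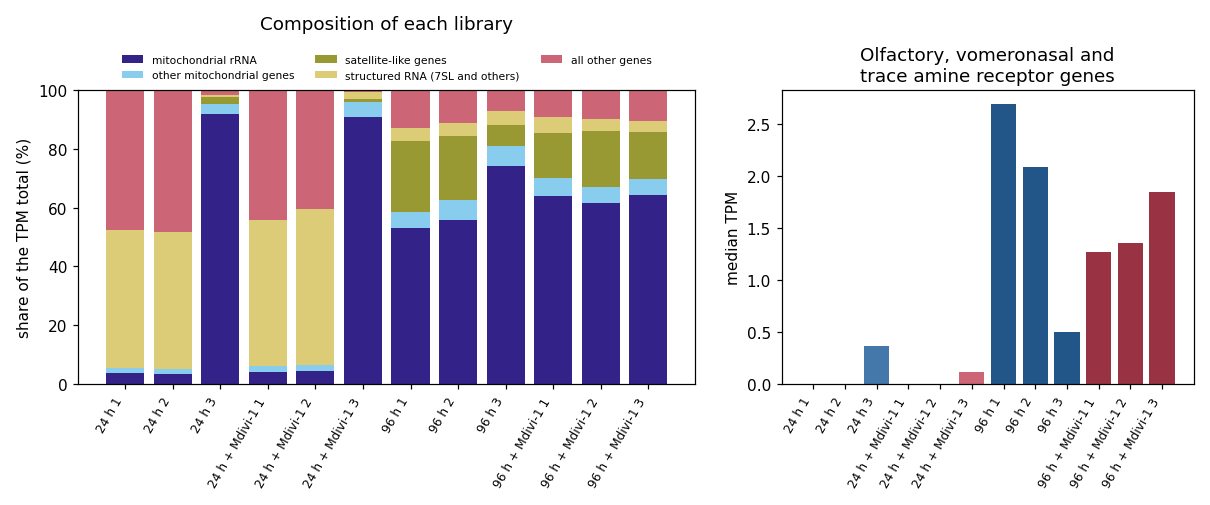
Left, bars give the share of the TPM total in percent in each of the 12 libraries, split by kind of RNA. Right, bars give the median TPM of 1430 such receptor genes, which is 0 in 24 h libraries 1 and 2 and up to 2.7 at 96 h.

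With Mdivi-1 at 24 h, genes of cell division, collagen and inflammatory signals were lower. Mki67 (ENSMUSG00000031004), a protein of dividing nuclei, fell from 16.1 ± 0.985 to 3.20 ± 0.826 TPM, a log2 change of -2.04 ± 0.19 (SE, n = 2 libraries per group, adjusted p = 0.00490). Il1b (ENSMUSG00000027398), the precursor of interleukin-1β, fell from 51.8 ± 0.0291 to 13 ± 1.61 TPM (-1.92 ± 0.17, adjusted p = 0.00490). Arg1 (ENSMUSG00000019987), the arginase that competes for the substrate of nitric oxide synthase, fell from 56.9 ± 15.4 to 5.23 ± 2.12 TPM (-3.23 ± 0.41, adjusted p = 0.0142). In the fit without both 24 h number 3 libraries, chosen after seeing the data, 58 genes fell and 0 rose of 19631. With background subtracted and rescaled in the same libraries, 0 genes were called. Median-of-ratios scaling of 24 h libraries 1 and 2 alone gave 550 higher and 850 lower. The planned fit of all 12 libraries called 0 genes by limma, with 15 at an unadjusted p under 0.05, and there the SE of Il1b was 2.46 around -1.33. Leaving out number 3 without Mdivi-1 alone gave 5 genes, all lower. That setting keeps number 3 with Mdivi-1, which holds almost no messenger RNA, so lower values were built in (median -0.77 log2). Leaving out number 3 with Mdivi-1 alone gave 0 genes and a median of 0.19.

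Inflammatory signals fell in part. Ptgs2 (ENSMUSG00000032487), the inducible enzyme of prostaglandin synthesis, fell from 7.66 ± 1.19 to 1.76 ± 0.392 TPM (-1.65 ± 0.16, adjusted p = 0.00490). Ccl2 (ENSMUSG00000035385), which draws monocytes, fell from 292 ± 32.3 to 123 ± 15.2 TPM (-1.24 ± 0.20, adjusted p = 0.0346), and the neutrophil attractant Cxcl2 (ENSMUSG00000058427) from 5.05 ± 0.376 to 2.11 ± 0.352 (-0.96 ± 0.15, adjusted p = 0.0314). Cxcl5 (ENSMUSG00000029371), of the same class, fell from 6.13 to 0.340 TPM (-2.40 ± 0.39). Of 20 inflammatory cytokines 2 fell and 18 were not called, with 10 lower when adjusted over the list alone (camera adjusted p = 1.46e-14, and 0.00731 with an estimated correlation). Of 15 chemokines 2 fell and 13 were not called, with 8 lower adjusted over the list alone (camera adjusted p = 3.91e-13, and 0.0480 with an estimated correlation). The structured RNA share was higher with Mdivi-1 in these same libraries, and the share of other genes lower. All 9 fibroblast markers were lower in them too, by -1.20 to -2.67 log2.

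Several classical activation genes were not called at 24 h in the fit without both number 3 libraries. That fit shares 1 estimate of the spread with the 96 h libraries, so its SEs can exceed the spread at 24 h. Among 9 fibroblast markers the largest SE was 0.394 in it and 0.197 with 24 h libraries 1 and 2 alone. A gene not called was thus not shown to be unchanged. Tnf (ENSMUSG00000024401) was at 69.3 ± 4.28 TPM without and 41.6 ± 2.38 with Mdivi-1 (-0.72 ± 0.18, adjusted p = 0.184), and the interferon-induced chemokine Cxcl10 (ENSMUSG00000034855) at 24.6 ± 8.90 and 6.33 ± 0.747 (-1.77 ± 0.41, adjusted p = 0.129). Acod1 (ENSMUSG00000022126), the itaconate synthase, was at 536 ± 21.9 and 370 ± 35.4 (-0.54 ± 0.20). Nos2 (ENSMUSG00000020826), inducible nitric oxide synthase, was at only 1.76 ± 0.316 and 0.816 ± 0.0660 TPM (-0.60 ± 0.20), and Il6 (ENSMUSG00000025746) at 0.929 and 0.163 (-0.73 ± 0.25). The mannose receptor Mrc1 (ENSMUSG00000026712) was at 18.5 ± 2.13 and 25.9 ± 4.41 (0.46 ± 0.26), and the costimulatory Cd86 (ENSMUSG00000022901) at 7.71 and 7.27 (-0.08 ± 0.33). Il10 (ENSMUSG00000016529) was at 0.497 and 0.302 TPM and under the expression filter of the planned fit and of the fit without both number 3 libraries. Dnm1l (ENSMUSG00000022789), which encodes the drug target Drp1, was at 26.1 ± 1.87 and 23.8 ± 1.15 TPM (-0.12 ± 0.18, adjusted p = 1). Of 12 genes of nitric oxide and arginine use, 1 fell and 11 were not called, with 4 lower adjusted over the list alone (camera adjusted p = 4.95e-07, and 0.0415 with an estimated correlation). Of 17 inflammasome genes 1 fell and 16 were not called, with 4 lower adjusted over the list alone (camera adjusted p = 1.04e-04, and 0.0327 with an estimated correlation).

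Genes of cell division were among those that fell at 24 h. Of 39 genes of G2 and mitosis 9 fell and 30 were not called, while all 39 were lower adjusted over the list alone (median -1.37 log2, camera adjusted p = 2.94e-75, and 0.0103 with an estimated correlation). Plk1 (ENSMUSG00000030867), a kinase of mitosis, fell from 7.16 to 0.996 TPM (-2.03 ± 0.30), the topoisomerase Top2a (ENSMUSG00000020914) from 12.7 to 2.58 (-1.94 ± 0.24), and Ccnb2 (ENSMUSG00000032218), a cyclin of mitosis, by -2.09 log2. Rrm2 (ENSMUSG00000020649), which makes deoxynucleotides, fell from 21.9 ± 3.12 to 3.50 ± 0.564 TPM (-2.35 ± 0.23, adjusted p = 0.00490). Of 41 S phase genes 3 fell and 38 were not called, with 22 lower adjusted over the list alone (median -0.92, camera adjusted p = 3.48e-39, and 0.0381 with an estimated correlation). Uhrf1 (ENSMUSG00000001228) and Ccne1 (ENSMUSG00000002068) were among those that fell (-1.84 ± 0.31 and -1.33 ± 0.19). The linker histone Hist1h1a (ENSMUSG00000049539) had the largest fall of all, from 64.3 ± 1.29 to 5.83 ± 1.48 TPM (-3.27 ± 0.42, adjusted p = 0.0145). Hist2h3c2 (ENSMUSG00000081058) and Hist1h3g (ENSMUSG00000099517) fell by -2.84 and -2.83 log2. Of 23 replication histones 2 fell and 21 were not called, with 21 lower adjusted over the list alone (median -1.74, camera adjusted p = 1.09e-38, and 0.00494 with an estimated correlation). Fibroblast markers fell in the same libraries.

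Collagens and other fibroblast markers were present in these 24 h libraries and lower with Mdivi-1. Col1a1 (ENSMUSG00000001506), the main chain of type I collagen, fell from 129 ± 12.3 to 20 ± 7.59 TPM (-2.67 ± 0.29, adjusted p = 0.00932), Col1a2 (ENSMUSG00000029661) by -1.90 log2 and Col3a1 (ENSMUSG00000026043) from 15.0 to 1.82 TPM (-2.54 ± 0.35). Thbs1 (ENSMUSG00000040152), the matrix protein thrombospondin, fell from 160 ± 1.53 to 29.3 ± 2.41 (-2.41 ± 0.22, adjusted p = 0.00490). Gas1 (ENSMUSG00000052957), named for growth arrest, fell from 12.7 ± 0.517 to 1.33 ± 0.0556 (-2.56 ± 0.31). Of 9 fibroblast markers 3 fell and 6 were not called, while all 9 were lower adjusted over the list alone (median -1.61, camera adjusted p = 9.52e-30, and 0.0327 with an estimated correlation). Fscn1 (ENSMUSG00000029581), an actin bundler, and Tgm2 (ENSMUSG00000037820), a transglutaminase, fell from 49.1 to 12.4 and from 108 to 51.4 TPM.

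Scd2 (ENSMUSG00000025203), a fatty acid desaturase, fell from 63.2 ± 2.37 to 30.2 ± 2.13 TPM (-1.04 ± 0.13, adjusted p = 0.0143), and Phgdh (ENSMUSG00000053398), which opens serine synthesis, from 7.97 to 2.66 (-1.32 ± 0.22). Of 13 fatty acid synthesis genes 1 fell and 12 were not called, with 10 lower adjusted over the list alone (camera adjusted p = 3.89e-17, and 0.00494 with an estimated correlation). Of the 47 lists, 29 were called, 23 of them lower, and 11 were still called with an estimated correlation, all lower. The same test called 2 with background subtracted and rescaled (0 by fry, lowest adjusted p = 0.163) and 0 with libraries 1 and 2 alone (lowest adjusted p = 0.555). With all 12 libraries 22 lists were called (15 higher, 7 lower), and 0 with an estimated correlation (lowest adjusted p = 0.0894) or by fry. Leaving out 24 h library 2 without Mdivi-1 gave 36 lists, leaving out Mdivi-1 library 3 gave 35, and leaving out Mdivi-1 library 2 gave 14. Some lists called higher with all 12 libraries have a negative median, and the median of all genes was -0.18. Interferon-stimulated genes show this with a median of -0.23 and a mean of -0.23 against a test direction of higher. Both values lie below the median of all genes, so that median does not account for the direction. Its cause was not tested.

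**Figure D2:**
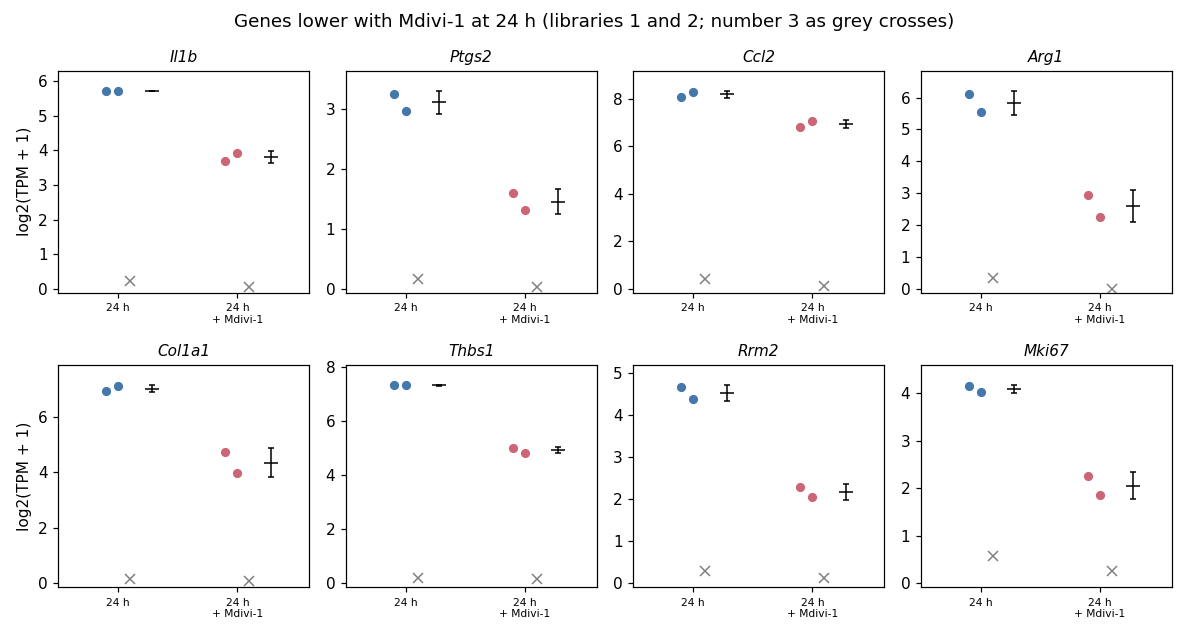
Dots give log2(TPM + 1) of 8 genes at 24 h without and with Mdivi-1 for libraries 1 and 2, bars the mean with SD of those (n = 2), and grey crosses the number 3 libraries. Il1b goes from 51.8 to 13 TPM and Thbs1 from 160 to 29.3.

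At 96 h Mdivi-1 raised single genes. Hmox1 (ENSMUSG00000005413), heme oxygenase, rose from 60.6 ± 3.49 to 201 ± 17.2 TPM, a log2 change of 1.71 ± 0.11 (SE, n = 3 libraries per group, adjusted p = 4.66e-04). Sqstm1 (ENSMUSG00000015837), the p62 receptor of selective autophagy, rose from 20.6 ± 1.94 to 45.1 ± 3.18 (1.09 ± 0.10, adjusted p = 0.00328). Lcn2 (ENSMUSG00000026822), which binds bacterial iron carriers, rose from 5.49 ± 1.51 to 16.9 ± 1.30 (1.49 ± 0.16, adjusted p = 0.00950). In the fit without both 24 h number 3 libraries, chosen after seeing the data, 20 genes rose and 8 fell, of which 7 and 1 have only placeholder symbols. With all 12 libraries 13 rose and 6 fell, and all 19 are placeholder genes at 0.1 TPM or less in 24 h libraries 1 and 2. Of the 28 calls, 6 are among those 19. The 96 h libraries are the same in both fits. The calls differ because the spread is shared with the 24 h libraries, and the genes tested differ too. In the test with known changes, 12.7% of the calls of the fit without both number 3 libraries were false at 96 h. With the 96 h libraries alone at a mean of at least 5 TPM, 1 gene was called.

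Some chaperones rose. Hspa1b (ENSMUSG00000090877), an inducible Hsp70, rose from 9.64 ± 4.28 to 37.5 ± 2.67 TPM (1.94 ± 0.26, adjusted p = 0.0317), its partner Dnajb1 (ENSMUSG00000005483) from 3.04 ± 0.456 to 7.07 ± 0.753 (1.0 ± 0.14, adjusted p = 0.0356), and Hsp90aa1 (ENSMUSG00000021270) from 43.4 ± 8.20 to 98.3 ± 10.3 (1.17 ± 0.13, adjusted p = 0.0147). Of 13 heat shock genes 3 rose and 10 were not called, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.87e-13, and 0.0229 with an estimated correlation). Of 29 targets of the antioxidant factor Nrf2, 2 rose and 27 were not called, with 5 higher adjusted over the list alone (camera adjusted p = 5.33e-10, adjusted p = 0.111 with an estimated correlation). Of 29 genes of the integrated stress response 1 rose and 28 were not called, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.41e-09, adjusted p = 0.111 with an estimated correlation). Ero1l (ENSMUSG00000021831), which forms disulfides in the endoplasmic reticulum, and Shmt2 (ENSMUSG00000025403), of mitochondrial one-carbon metabolism, rose from 14.1 to 25.7 and from 4.91 to 9.38 TPM. Slc48a1 (ENSMUSG00000081534), a heme transporter, rose from 7.06 to 12.1. The receptor background was 2.7, 2.09 and 0.498 TPM without Mdivi-1 and 1.27, 1.36 and 1.85 with it.

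Cdkn1a (ENSMUSG00000023067), the p21 brake of the cell cycle, rose from 13.7 ± 0.951 to 25.8 ± 3.18 TPM (0.87 ± 0.11, adjusted p = 0.0181), and the survival gene Bcl2a1a (ENSMUSG00000102037), which has near-identical copies, from 4.76 ± 2.64 to 16.2 ± 1.89 (1.67 ± 0.26, adjusted p = 0.0451). Cxcl2 rose from 95.6 ± 9.85 to 186 ± 21 (0.95 ± 0.12, adjusted p = 0.0198), and Saa3 (ENSMUSG00000040026), an acute phase protein, from 55.6 ± 9.60 to 104 ± 10.1 (0.89 ± 0.14, adjusted p = 0.0451). Plau (ENSMUSG00000021822), the urokinase, fell from 7.19 ± 0.935 to 3.14 ± 0.226 (-0.98 ± 0.11, adjusted p = 0.0150), the tubulin Tubb6 (ENSMUSG00000001473) from 21.5 ± 3.12 to 10.5 ± 1.40 (-0.96 ± 0.14, adjusted p = 0.0361), and Oaz1 (ENSMUSG00000035242), which restrains polyamine synthesis, from 19.6 ± 1.15 to 12.4 ± 0.985 (-0.62 ± 0.09, adjusted p = 0.0448). Cggbp1 (ENSMUSG00000054604), S100a1 (ENSMUSG00000044080) and Phf11b (ENSMUSG00000091649) fell by -0.77, -0.70 and -0.62 log2. Of 20 inflammatory cytokines 1 rose and 19 were not called, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00745, adjusted p = 0.199 with an estimated correlation).

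None of the tested genes fixed beforehand was called at 96 h. Il1b was at 389 ± 81.4 and 538 ± 27.9 TPM (0.49 ± 0.14, adjusted p = 0.422), Ptgs2 at 131 ± 19.1 and 181 ± 14.2 (0.47 ± 0.13, adjusted p = 0.424), Il6 at 3.43 ± 1.02 and 8.25 ± 0.820 (1.08 ± 0.20, adjusted p = 0.101), and Tnf at 26.8 ± 4.91 and 15.1 ± 2.58 (-0.79 ± 0.15, adjusted p = 0.102). Nos2 stood at 62.0 ± 12.6 and 46.4 ± 6.49 (-0.40 ± 0.16), Acod1 at 54.7 ± 14.2 and 40.7 ± 4.32 (-0.39 ± 0.16), and Cxcl10 at 28.4 ± 14.0 and 23.3 ± 5.08 (-0.17 ± 0.33). Arg1 was near the background at 1.09 and 1.06 (0.04 ± 0.33), as were Mrc1 (-0.07), Cd86 (-0.24) and Il10, at 1.38 and 0.950 TPM. Dnm1l was at 2.7 ± 0.555 and 2.76 ± 0.263 (0.03 ± 0.14). With the 96 h libraries alone at a mean of at least 5 TPM, Hmox1 was the only gene called (1.71 ± 0.12, adjusted p = 0.0240). It was also the only one after background subtraction there (1.77 ± 0.16, adjusted p = 0.0107). Of the 47 lists 20 were called (12 higher, 8 lower) and only heat shock with an estimated correlation. That call was lost with an estimated correlation with the 96 h libraries alone (adjusted p = 0.185), with background subtracted there (0.821) and with it subtracted and rescaled (0.806), where 0 lists were called in this way. For lists the planned fit called 0, and 25 without 96 h library 3 of the group without Mdivi-1. The count of 19 genes became 32, 40 and 60 without 96 h library 1, 2 or 3 of the group without Mdivi-1. It became 34 and 40 without Mdivi-1 library 1 or 3 of 96 h.

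**Figure D3:**
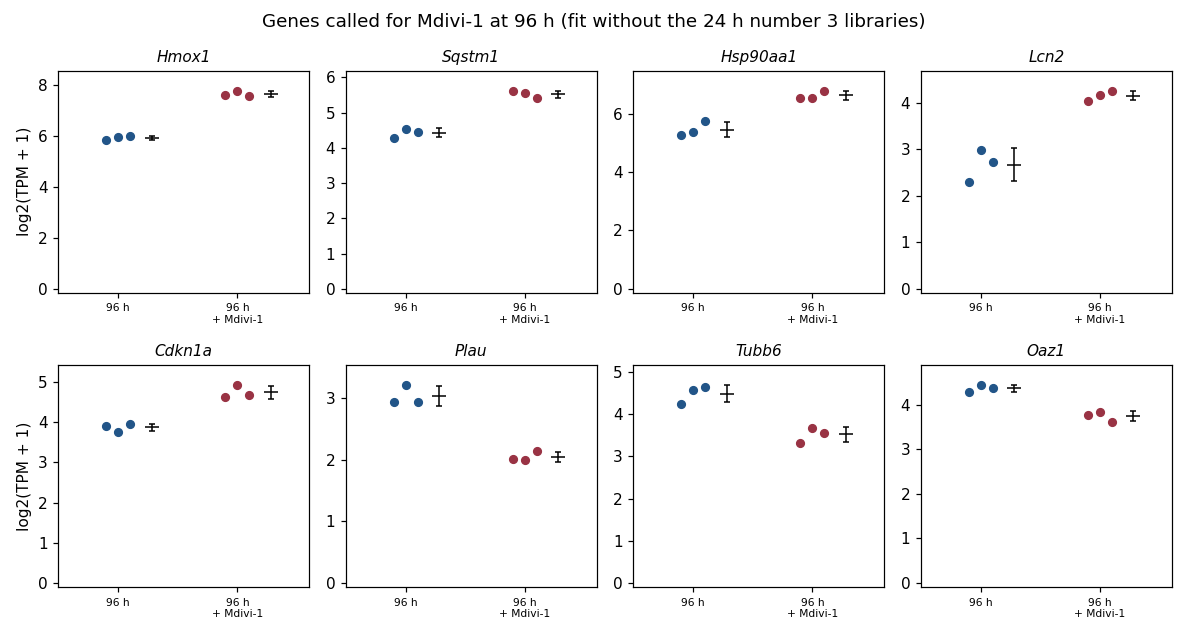
Dots give log2(TPM + 1) of 8 genes at 96 h without and with Mdivi-1, 1 per library, and bars the mean with SD (n = 3). Hmox1 goes from 60.6 to 201 TPM and Plau from 7.19 to 3.14.

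In the fit without both 24 h number 3 libraries, the effect of Mdivi-1 differed between 96 h and 24 h for some inflammatory and stress genes. Time cannot be told apart there from the kind of library or from another source of the cells. Mitochondrial ribosomal RNA took 3.37% to 4.56% in 24 h libraries 1 and 2 and 53.1% to 74.2% at 96 h. Il1b fell at 24 h and was not called at 96 h, a difference of 2.40 ± 0.22 log2 (SE, adjusted p = 0.00514). Ptgs2, with the same calls, and Cxcl2, which fell at 24 h and rose at 96 h, differed too (2.12 ± 0.21 and 1.92 ± 0.19, adjusted p = 0.00514 for both), as did Il1a (ENSMUSG00000027399), the other interleukin-1 (1.41 ± 0.21). Lcn2 was at 121 ± 0.601 TPM without and 59.7 ± 0.369 with Mdivi-1 at 24 h and rose at 96 h (2.5 ± 0.25, adjusted p = 0.00514). Hmox1 was at 824 ± 86.8 and 716 ± 88.6 TPM at 24 h (1.92 ± 0.18, adjusted p = 0.00514). In the fit without both 24 h number 3 libraries, chosen after seeing the data, the difference was higher in 22 genes and lower in 2. With background subtracted and rescaled in the same libraries, it was higher in 1 and lower in 1. With all 12 libraries limma called 0, with 123 at an unadjusted p under 0.05. Leaving out 96 h library 1 or 3 without Mdivi-1 gave 1 and 25 calls, and leaving out Mdivi-1 library 1 or 3 of 96 h gave 12 and 8.

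Some of these differences are of genes that had little signal left at 96 h. Hist1h1a (3.90 ± 0.54, adjusted p = 0.0350) was at 0.571 and 1.5 TPM at 96 h, Col1a1 (2.58 ± 0.38, adjusted p = 0.0357) at 0.637 and 0.501, Thbs1 (2.43 ± 0.29, adjusted p = 0.0158) at 1.04 and 1.01, Gas1 (2.57 ± 0.39) at 1.20 and 1.18, Rrm2 (2.08 ± 0.30) at 0.772 and 0.475, and Fscn1 (2.28 ± 0.33) at 0.952 and 1.47. Above the receptor background at 96 h were Hsp90aa1 (1.44 ± 0.21), Saa3 (1.81 ± 0.21), Cdkn1a (1.32 ± 0.17), Shmt2 (1.38 ± 0.20) and Phgdh (2.26 ± 0.29). Plau was the only gene with a proper symbol in the other direction (-1.35 ± 0.18, adjusted p = 0.0290). Not called were Arg1 (3.27 ± 0.53, adjusted p = 0.0633), Il6 (1.81 ± 0.32), Cxcl10 (1.59 ± 0.52), Nos2 (0.20 ± 0.25), Acod1 (0.14 ± 0.26), Tnf (-0.07 ± 0.24), Mrc1 (-0.53 ± 0.34), Cd86 (-0.16 ± 0.42) and Dnm1l (0.15 ± 0.23).

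Among lists, the difference was higher for cytokines and for stress genes. Of 20 inflammatory cytokines 4 were higher and 16 not called, with 7 adjusted over the list alone (camera adjusted p = 8.11e-13, and 0.0155 with an estimated correlation). Of 13 heat shock genes 1 was higher and 12 not called, with 5 adjusted over the list alone (0.0155 with an estimated correlation). Of 29 integrated stress response genes 2 were higher and 27 not called, with 8 adjusted over the list alone (0.0350 with an estimated correlation). The lists of cell division and fibroblast markers restate the 24 h fall where their genes had little signal at 96 h, as with Plk1 at 0.904 and 0.552 TPM and Ccnb2 at 1.23 and 0.389. The G2 and mitosis list had 0 of 39 called and 23 adjusted over the list alone (0.0350 with an estimated correlation). Replication histones had 1 of 23 and 12 adjusted over the list alone (0.0162 with an estimated correlation). Fibroblast markers had 1 of 9 and 9 adjusted over the list alone (camera adjusted p = 1.71e-21, adjusted p = 0.0506 with an estimated correlation). In all, 24 lists were called (20 higher, 4 lower) and 6 with an estimated correlation. With background subtracted and rescaled, 0 were called with an estimated correlation (lowest adjusted p = 0.758) or by fry (0.860). The planned fit called 5 and 0 with an estimated correlation (lowest adjusted p = 0.999), and leaving out 1 library gave from 3 (96 h library 2 without Mdivi-1) to 30 (24 h library 3 without Mdivi-1). Across 17668 genes the effects at 24 h and 96 h correlated at 0.0257, and at 0.0324 without both number 3 libraries, where genes are not independent replicates.

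From 24 h libraries 1 and 2 to the 96 h libraries without Mdivi-1, most macrophage identity genes fell. Some inflammatory genes rose, while Tnf and Acod1 fell. Without both number 3 libraries, camera called no list with an estimated correlation (lowest adjusted p = 0.0567). Time cannot be told apart here from library composition or from another source of the cells. Pycard, which RAW264.7 is known to lack, was at 26.0 to 29.0 TPM in 24 h libraries 1 and 2 and at most 1.93 at 96 h. Apoe (ENSMUSG00000002985), the lipid carrier abundant in resting macrophages, went from 1363 ± 113 TPM to 0.310 ± 0.152 (-10.03 ± 0.15, SE, n = 2 and 3, adjusted p = 5.76e-11). Adgre1 (ENSMUSG00000004730), which encodes the macrophage marker F4/80, fell from 1069 ± 59.0 to 2.58 ± 0.741 (-8.24 ± 0.17). Nos2 rose from 1.76 ± 0.316 to 62.0 ± 12.6 TPM (4.50 ± 0.18, adjusted p = 6.17e-09), and Csf3 (ENSMUSG00000038067), the granulocyte growth factor, from 0.103 to 65.2 ± 9.03 (5.90 ± 0.15). In the fit without both 24 h number 3 libraries, chosen after seeing the data, 7128 genes rose and 9214 fell of 19631, and 88.7% of the rises were at 0.1 TPM or less in 24 h libraries 1 and 2. With all 12 libraries 4936 rose and 67 fell. Of those 4936, 94.0% were at 0.1 TPM or less in 24 h libraries 1 and 2, 3673 have placeholder symbols and 496 are olfactory, vomeronasal or trace amine receptor genes.

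The planned fit without Mdivi-1 still called Nos2 (4.94 ± 1.46, adjusted p = 0.0292), Csf3 (5.92 ± 1.36) and Ifi202b (ENSMUSG00000026535), an interferon-induced DNA sensor listed at 0 in both 24 h libraries 1 and 2 without Mdivi-1 and at 44.9 ± 10.9 TPM at 96 h. Other rises were of Hist1h2al (ENSMUSG00000091383), listed at 0 in those libraries, and of the ribosomal RNA pieces Mir6236 (ENSMUSG00000098973) and n-R5s193 (ENSMUSG00000064798) (7.01 and 7.71). Hist1h2bh (ENSMUSG00000064168) fell by -3.78 log2, the mitochondrial import chaperone Timm10 (ENSMUSG00000027076) by -2.78, Sirpb1c (ENSMUSG00000074677) by -3.03, Bvht (ENSMUSG00000098098) by -2.36 and Tmem254a (ENSMUSG00000072676) by -2.28. Apoc2 (ENSMUSG00000002992), at 27.8 TPM at 24 h, was listed at 0 at 96 h. That fit did not call Il1b (4.70 ± 2.46), Ptgs2 (4.91 ± 2.0), Il6 (1.37 ± 0.66), Tnf (0.61 ± 2.13), Arg1 (-3.02 ± 1.16), Acod1 (-0.38 ± 2.81), Cxcl10 (1.56 ± 1.76), Mrc1 (-1.44 ± 1.26), Cd86 (-1.01 ± 0.87) or Dnm1l (-1.36 ± 1.38). Its count of 5003 became 0 without library 1 or 2 of either 24 h group. It became 2 and 12 without 96 h library 1 or 2 of the group without Mdivi-1, and 11503 without number 3 of 24 h.

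Without both number 3 libraries Ptgs2 rose (3.93 ± 0.15), Il1b rose from 51.8 ± 0.0291 to 389 ± 81.4 TPM (2.86 ± 0.15), and Il6 rose (1.17 ± 0.23). Acod1 fell from 536 ± 21.9 to 54.7 ± 14.2 (-3.30 ± 0.18), Arg1 from 56.9 ± 15.4 to 1.09 ± 0.796 (-4.85 ± 0.37), Dnm1l from 26.1 ± 1.87 to 2.7 ± 0.555 (-2.88 ± 0.16) and Tnf from 69.3 ± 4.28 to 26.8 ± 4.91 (-1.35 ± 0.17), in libraries where the share of other genes was lower at 96 h. Cxcl10 was not called (0.12 ± 0.37). Tgfbi (ENSMUSG00000035493), a matrix protein of macrophages, fell from 651 to 0.539 TPM, the complement gene C1qb (ENSMUSG00000036905) from 725 to 1.04, Npy (ENSMUSG00000029819) from 303 to 0.0903 and Pla2g7 (ENSMUSG00000023913) from 398 to 0.510. All 38 lysosome genes fell (median -5.17, camera adjusted p = 1.13e-14, adjusted p = 0.0567 with an estimated correlation). Of 19 macrophage identity genes 18 fell and 1 rose (median -4.71, adjusted p = 0.0567 with an estimated correlation). All 13 messenger RNAs of the mitochondrial genome rose (median 1.41, camera adjusted p = 1.0e-05, adjusted p = 0.119 with an estimated correlation), beside mitochondrial ribosomal RNA. Adjusting over each list alone gave 38, 18 and 13 calls in these directions.

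With Mdivi-1 some inflammatory genes rose more from 24 h to 96 h in the fit without both number 3 libraries, namely Il1b, Ptgs2 and Cxcl2, while the difference was not called for Nos2, Acod1, Tnf or Cxcl10 and for 0 genes in the planned fit. Il1b went from 13 ± 1.61 to 538 ± 27.9 TPM (5.27 ± 0.15 without both number 3 libraries, adjusted p = 1.34e-09), Ptgs2 from 1.76 ± 0.392 to 181 ± 14.2 (6.05 ± 0.15) and Cxcl2 from 2.11 ± 0.352 to 186 ± 21 (5.91 ± 0.13). The planned fit also called these rises (6.52 ± 2.46, 6.52 ± 2.0 and 6.42 ± 1.93, adjusted p = 0.0454, 0.0186 and 0.0181). It called those of Nos2 (4.95 ± 1.46), Csf3 (6.24 ± 1.36) and Il6 (2.94 ± 0.66) as well. Its 24 h mean includes number 3 with Mdivi-1, which holds almost no messenger RNA, with Il1b at 0.0438 and Cxcl2 at 0.0846 TPM. Larger rises of Il1b and Cxcl2 were thus built in, and the calls are not independent support. In that fit mt-Ty (ENSMUSG00000064350) fell by -4.56 log2, Tmem86a (ENSMUSG00000010307) by -4.06, Timm10 by -2.60 and Spsb3 (ENSMUSG00000024160) by -2.24. Not called in it were Tnf (0.26 ± 2.13), Arg1 (-0.71 ± 1.16), Acod1 (-0.34 ± 2.81), Cxcl10 (2.58 ± 1.76), Mrc1 (-1.75 ± 1.26), Cd86 (-1.15 ± 0.87) and Dnm1l (-1.21 ± 1.38). This does not mean that they were unchanged. With Mdivi-1, Acod1 went from 370 TPM in 24 h libraries 1 and 2 to 40.7 at 96 h, and Dnm1l from 23.8 to 2.76. In the same libraries Arg1 went from 5.23 to 1.065, Cd86 from 7.27 to 0.926 and Cxcl10 from 6.33 to 23.3. Tnf fell in the fit without both number 3 libraries. Without both number 3 libraries 6938 genes rose and 8642 fell, with 86.6% of the rises at that level. With all 12 libraries 5579 rose and 36 fell, of which 90.6% of the rises were at 0.1 TPM or less in 24 h libraries 1 and 2. That count of 5615 became 0 without Mdivi-1 library 1 or 2 of 24 h, 9914 without its number 3, and 90 without Mdivi-1 library 3 of 96 h.

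With Mdivi-1 too, all 38 lysosome genes fell from 24 h to 96 h (median -5.02) and 10 of 13 messenger RNAs of the mitochondrial genome rose, while Apoe fell by -9.72 log2. Lists called were 38 without Mdivi-1 (1 higher, 37 lower) and 34 with it (1 higher, 33 lower), and 0 with an estimated correlation (lowest adjusted p = 0.0567 and 0.0531). The planned fit called 33 in each case, 32 and 33 of them lower, and 0 with an estimated correlation (lowest adjusted p = 0.709 and 0.768).

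**Figure D4:**
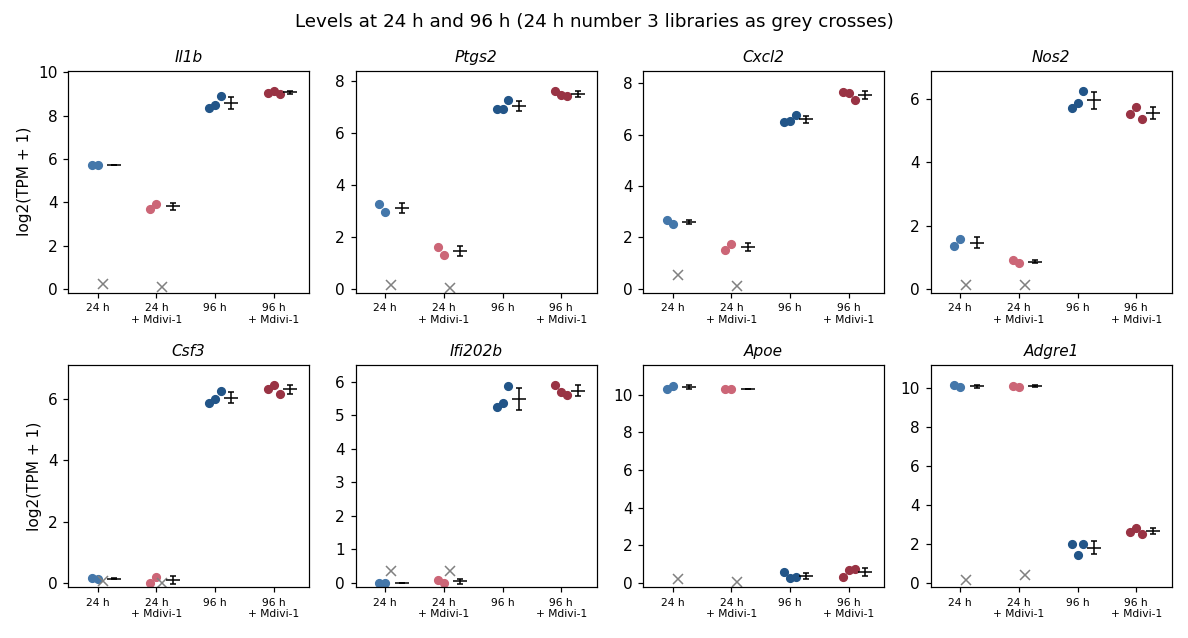
Dots give log2(TPM + 1) of 8 genes in the 4 groups, 1 per library, with grey crosses for the 24 h number 3 libraries and bars for the mean with SD of the others. Nos2 goes from 1.76 to 62.0 TPM without Mdivi-1 and Apoe from 1363 to 0.310.

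The way TPM is scaled bears on these numbers, because a few RNAs fill most of each 96 h library. At a mean of at least 5 TPM and without both number 3 libraries the median gene changed by -2.58 log2 from 24 h to 96 h without Mdivi-1 and -2.43 with it. With background subtracted and the rest rescaled it changed by 0.39 and 0.46, with 2732 genes higher and 2642 lower without Mdivi-1. On that scale Nos2 rose by 6.13 log2, Il1b by 5.70 and Csf3 by 6.64, while Apoe fell by -8.16 and Adgre1 by -6.84. Tnf, lower in TPM, was higher on that scale (1.39 ± 0.25, adjusted p = 0.00286), and Acod1 was not called (-0.43 ± 0.24). For Mdivi-1 that scale kept 5 of the 28 calls of 96 h, among them Hmox1 (1.78 ± 0.11, adjusted p = 8.64e-04) and Sqstm1 (1.22 ± 0.14), and 2 of the 24 differences. At 24 h limma called 0 there with 115 at an unadjusted p under 0.05, and Il1b had -1.54 ± 0.20 (adjusted p = 0.0993). At 24 h, median-of-ratios scaling of libraries 1 and 2 alone moved the median Mdivi-1 effect from -0.22 to 0.03. The calls went from 74 higher and 2350 lower to 550 and 850. All 58 genes that fell were also lower there, but they were picked from these same libraries, so this is not independent support.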

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

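The tests of the cause of the 24 h fall were chosen only after the result was seen, while the tests by regrouping samples were written before. In the fit without both 24 h number 3 libraries, Il1b and Ptgs2 were called lower with Mdivi-1 at 24 h and not called at 96 h. Lcn2 and Hmox1 were called higher only at 96 h, and Cxcl2 lower at 24 h and higher at 96 h. The planned fit called 0 genes for this difference. With background subtracted and rescaled, 2 genes were called for it and 0 for Mdivi-1 at 24 h. Library composition differed between the times, and another source of the cells in 24 h libraries 1 and 2 was not excluded. Pycard, which RAW264.7 is known to lack, was at 26.0 to 29.0 TPM there and at most 1.93 at 96 h. Time cannot be told apart from either. Without both 24 h number 3 libraries, limma gave adjusted p = 0.00514 for Il1b, 0.00514 for Ptgs2, 0.00514 for Lcn2, Hmox1 and Cxcl2, and 0.0290 for Plau, which moved the other way. Thbs1 (0.0158), Hist1h1a (0.0350), Col1a1 (0.0357) and Gas1 (0.0497) belong to the same 24 genes, but these were under 2 TPM at 96 h in both groups, so their difference is mostly the 24 h fall.

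The planned fit of all 12 libraries called 5 lists for this difference. They were messenger RNAs of the mitochondrial genome (median -0.45 log2, camera adjusted p = 0.00137, lower), S phase genes (median 0.38, 0.0103, higher), G2 and mitosis genes (median 0.78, 2.02e-14, higher), replication histones (median 0.79, 0.00708, higher) and fibroblast markers (median 1.12, 2.63e-04, higher). Each had 0 members called, and adjusted p = 0.999 with an estimated correlation. Without both number 3 libraries the G2 and mitosis list and the histones were called with an estimated correlation too, though Plk1, Ccnb2 and other members had little signal at 96 h, and the mitochondrial messenger RNAs were not (0.141).

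The 24 h fall of fibroblast markers and cell division genes could come from a smaller share of fibroblast-type cells in the Mdivi-1 libraries. If so, the markers should fall by the same factor. The 9 markers above 5 TPM fell by different amounts, from -1.20 log2 for Dcn (ENSMUSG00000019929) to -2.67 for Col1a1, a range of 7.50 times the largest SE in the fit of these 4 libraries alone. In the fit without both number 3 libraries, whose SEs are larger, the range was 3.75 times the largest SE, under the 4 times set for excluding it, so whether this is the cause cannot be told. How many of these markers RAW264.7 cells make themselves was not tested. A higher share of structured RNA is excluded as the whole cause, because the S phase list, which was the least changed, still had a median of -0.73 after median-of-ratios scaling.

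Regrouping the samples tested the counts of the planned fit against other ways to divide the same libraries. Where the real count is 0 every grouping reaches it, so 10 of 10 for genes at 24 h, 10 of 10 for lists at 96 h and 100 of 100 for genes of the difference were fixed beforehand and say nothing about chance. At 24 h the other groupings gave up to 8848 genes. Groupings that placed both number 3 libraries together gave 8848, 7878, 4805 and 4132 and every other gave 0, so the number 3 libraries set this structure. The 4 groupings that part every pair of equal numbers all gave 0 genes and, for the lists, 22 for the real grouping against 10, 1 and 16. Over all groupings, 5 of 10 gave at least as many lists at 24 h. At 96 h, 8 of 10 gave at least 19 genes. For the difference, 79 of 100 gave at least 5 lists, so chance is not excluded for these lists. For time, 1 of 10 reached the real count without Mdivi-1 and 1 of 10 with it. A set of 10 groupings cannot give a share under 0.05.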

How the results depend on the processing

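Each planned choice was changed 1 at a time, and the cause of a moved count was not tested unless stated. For the Mdivi-1 effect at 24 h the planned fit called 0 genes, and most planned changes kept 0. The replicate block over all groups gave 2. Without both number 3 libraries it was 58 (74 at a mean TPM of at least 5), with 24 h libraries 1 and 2 alone 2424, with median-of-ratios scaling of these 1400, and with sample weights, which did not converge, 5100. Leaving out 1 library gave 0 to 5.

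For the Mdivi-1 effect at 96 h the count of 19 became 0 with pseudocount 0.1, at a mean TPM of at least 5, with median-of-ratios scaling, and with only the 96 h groups fitted. It was 61 with TPM above 0 in any sample, 6 with quantile normalization, 31 with the replicate block over all groups, 2 with the block within time, 30 with robust variance and 5847 with sample weights. It was 28 without both number 3 libraries, 51 in that fit at a mean TPM of at least 5, 1 with 96 h libraries alone at that mean, 1 with background subtracted there, and 6 with background subtracted and rescaled. Leaving out 1 library gave 14 to 60.

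For the difference of the Mdivi-1 effect between 96 h and 24 h the count of 0 became 1 with either replicate block, 2 with robust variance, 4669 with sample weights, 24 without both number 3 libraries, 34 in that fit at a mean TPM of at least 5, and 2 with background subtracted and rescaled. Leaving out 1 library gave 0 to 25.

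For 96 h against 24 h without Mdivi-1 the count of 5003 became 0 with pseudocount 5, 11211 with TPM above 0 in any sample, 1 at a mean TPM of at least 5, 47 with median-of-ratios scaling, 31 with quantile normalization (87.1% higher against 98.7%), 71 when rescaled after removing dominant genes, 5 with only the groups of the contrast, 16794 with sample weights and 16342 without both number 3 libraries. Leaving out 1 library gave 0 to 11503. With Mdivi-1 the count of 5615 became 10, 12829, 1, 80, 24 (83.3% higher against 99.4%) and 112 in the order of the changes from pseudocount 5 to rescaling, with 16676 for sample weights and 15580 without both number 3 libraries. Leaving out 1 library gave 0 to 9914. Median-of-ratios scaling moved the all-gene median to 0.47 without and 0.54 with Mdivi-1, and rescaling to 1.21 and 1.56. For time the replicate block over all groups gave 6045 and 6391, although the numbers at 96 h did not pair (-0.123, -0.0248 and -0.257).

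The gene lists at 24 h (22) became 0 with an estimated correlation and 14 with quantile normalization, with 14 to 36 on leaving out 1 library. The gene lists at 96 h (0) became 8 at a mean TPM of at least 5, 5 with median-of-ratios scaling, 6 with quantile normalization, 20 without both number 3 libraries, 6 with 96 h libraries alone, 5 with background subtracted there and 13 with it subtracted and rescaled, with 0 to 25 on leaving out 1 library. The gene lists, difference of the Mdivi-1 effect (5) became 0 with an estimated correlation, 8 at a mean TPM of at least 5, 16 with median-of-ratios scaling, 2 with quantile normalization, 24 without both number 3 libraries and 14 with background subtracted and rescaled, with 3 to 30 on leaving out 1 library.

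The correlation of the Mdivi-1 effects (0.0257) was 0.0488 at a mean TPM of at least 5, 0.00917 with pseudocount 0.1, 0.00534 with median-of-ratios scaling, 0.0433 with background subtracted and rescaled, -0.452 over the 19 genes called, and 0.392 over the 84 called without both number 3 libraries, with -4.07e-04 to 0.0284 on leaving out 1 library. Genes are not independent replicates in it.

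Direction was reversed for 6 named genes over time. Tnf without Mdivi-1 fell by -1.5 with sample weights and -1.35 without both number 3 libraries, at either mean, and with Mdivi-1 by -1.45, -1.42 and -1.42. Hsp90ab1 without Mdivi-1 fell by -1.79, -1.83 and -1.83. Sqstm1 with Mdivi-1 fell by -2.25, -2.32 and -2.32. With background subtracted and rescaled, Hspa8, Nars and Pgk1 without Mdivi-1 rose by 0.78, 0.62 and 0.68. In that last table the removal of mitochondrial and structured RNA raises every other gene at 96 h by construction.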

Other observations

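The tests of background, of messenger RNA share and of the source of the cells were chosen only after the results were seen. With libraries 1 and 2 of 24 h alone and median-of-ratios scaling, some genes rose with Mdivi-1. The TPM values given are as deposited, while the log2 changes are after that scaling. It moved the median effect from -0.22 to 0.03, so the log2 changes are larger than the TPM values give. Mt2 (ENSMUSG00000031762), a metallothionein that binds zinc and copper, rose from 25.1 ± 3.52 to 48.7 ± 4.89 TPM (1.21 log2). Hyal1 (ENSMUSG00000010051), a lysosomal hyaluronidase, rose from 8.01 to 15.7 (1.15), and Cdkn1c (ENSMUSG00000037664), a brake of the cell cycle, from 22.5 to 39.4 (1.05). Akr1b8 (ENSMUSG00000029762) and Ednrb (ENSMUSG00000022122) rose by 1.01 and 1.0. Of 38 lysosome genes 10 rose, 1 fell and 27 were not called (11 adjusted over the list alone), and of 21 glycolysis genes 9 rose. These 4 libraries leave 2 residual degrees of freedom, 14.2% of calls were false in the test with known changes, and 0 of 26 lists were called with an estimated correlation (lowest adjusted p = 0.478).

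On the background-subtracted scale, most inflammatory cytokines were higher and lysosome genes lower at 96 h than at 24 h without Mdivi-1. The lists were not tested against each other. With an estimated correlation, camera called 0 of 42 lists over time (lowest adjusted p = 0.728 without and 0.770 with Mdivi-1). Ccl3 (ENSMUSG00000000982) and Ccl4 (ENSMUSG00000018930), chemokines of activated macrophages, rose by 4.66 and 4.29 log2. Of 16 inflammatory cytokines 11 rose, 3 fell and 2 were not called (camera adjusted p = 0.00137, adjusted p = 0.728 with an estimated correlation). All 37 lysosome genes tested fell (median -3.04). Ribosomal proteins, lower in TPM, had 37 higher and 9 lower of 76. With Mdivi-1 the heat shock list had 8 higher and 1 lower of 11, led by Hspa1b (5.53). The cause of the shift between scales was not tested.

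A low signal over silent receptor genes runs through 8 of the 12 libraries. Genomic DNA in these libraries passed the range set for its test, but not closely. Cells of a male line hold 1 X chromosome, and protein-coding genes at 0 in 24 h libraries 1 and 2 had a median X to autosome ratio of 0.395 over the 8 libraries, with 7 between 0.3 and 0.7 and 1 at 0. The 95% bootstrap intervals lay below 0.5, the value for 1 X chromosome, in 7 of the 8 libraries, and only that of 96 h library 3 without Mdivi-1 (0.305 to 0.521) reached it, so what lowers the ratio stays open. A run over all silent genes gave medians of 0 and was narrowed to protein-coding genes for that reason. Deeper sequencing is excluded, since the lowest mean TPM of the receptors in the 8 libraries was 11.2 times the highest in the other 4.

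Macrophage genes were low at 96 h beyond the loss of messenger RNA share. With background subtracted and the rest rescaled, the macrophage identity list (18 genes) lay -3.37 log2 from the median of all genes, which excludes that loss as the whole cause. Another source of the cells in 24 h libraries 1 and 2 cannot be told from time with these samples. It is only a hypothesis, raised because RAW264.7 is known to lack Pycard (ENSMUSG00000030793), the inflammasome adaptor. Pycard was at 26.0 to 29.0 TPM in those 4 libraries and at most 1.93 at 96 h. These values met the range set for another source of the cells, a range chosen after the result was seen. They do not settle it, because source and time change together in these libraries.

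Mdivi-1 left mitochondrial lists without a clear change. At 24 h without both number 3 libraries, messenger RNAs of the mitochondrial genome had 0 of 13 called (median 0.19, camera adjusted p = 6.60e-06, adjusted p = 0.166 with an estimated correlation). At 96 h the median was -0.25 (adjusted p = 0.569 with an estimated correlation). ATP synthase genes at 96 h had 0 of 15 called and 2 lower adjusted over the list alone (camera adjusted p = 4.73e-05, adjusted p = 0.147 with an estimated correlation).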
